A study of Homo sapiens with 647 samples.

How the data were processed

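The series held SMART-Seq2 RNA sequencing of 647 libraries from the estrogen receptor positive breast cancer line T47D, in a parental line and lines carrying GFP, FGFR1, FGFR2 (wild type, M538I, N550K or K660N) or FGF3. Per the labels, cells were treated 48 h after plating and harvested 24 h later. The treatments were DMSO, fulvestrant (Fulv, 100 nM), palbociclib (Palbo, 1 µM), the FGFR inhibitor FIIN-3 (100 nM), the MEK inhibitor trametinib (Tram, 500 nM), FGF2 and combinations of these; the dose of FGF2 was not given in the sources used here. The FGF3 line had no arms with FGF2, and its untreated group in set 2 was labelled control, without a statement that DMSO was added. Per the submitters' processing notes, reads were aligned with STAR to hg19; the program that counted reads, its annotation and the versions were not given in the sources used here.

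The first deposited table held read counts per gene (count) for 54592 genes in all 647 libraries. The second deposited table held values on the scale log2(TPM + 1), since 2 to the power of the value minus 1 summed to 1e+06 in each library; 91 of its columns, the DMSO and fulvestrant libraries, entered an alternative test and 556 columns were not used. The planned log2(value + 1) of that table was therefore not taken, and its values were used as they were. Gene type, length, GC content and pseudoautosomal membership came from GENCODE v29, which is on GRCh38 and not on the build of the counts.

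The numbers in the sample titles ran through 2 times, and each run was treated as a set: set 1 held 376 libraries (median total count 7570052.5, range 512961 to 13012180, median 18906 genes detected) and set 2 held 271 (median 2887186, range 619509 to 4804935, median 16526 genes). There were 110 combinations of line and treatment with 4 to 12 libraries over both sets, of which 88 had 6 and 20 had fewer. Per line there were 79 parental, 81 GFP, 82 FGFR1, 82 FGFR2 wild-type, 81 M538I, 95 N550K, 82 K660N and 65 FGF3 libraries. The FGF3 line was read least deeply, with a median total of 3403813 in set 1. Every treatment except FIIN-3 alone was in 1 set only, so comparisons were made within a set. The labels do not say whether the libraries of a group were grown as separate cultures; p-values then measure only the spread between these samples, which may be technical. Several comparisons share the same 6 GFP DMSO libraries and are not independent of each other.

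Before the data were examined, the 41 comparisons, 12 gene lists (215 genes), the test, the threshold, the named-gene rule and the first set of alternatives were fixed. Each comparison used only its own libraries in edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest) under R 4.3.3, with line as an additive factor where several lines were pooled. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called higher or lower, or said to rise or fall. Values given as a ± b are log2 fold changes with their standard errors. Except for small counts, called genes are given in percent of the genes tested in the reported comparison, and the same denominator is used for alternatives. Differences between line classes were tested as the interaction of treatment and line class.

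Genes named in the text are FGFR1, FGFR2, FGF3 and FGF2, 13 marker genes, up to 4 members of each list, and per comparison up to 10 genes per direction with the largest change among those with adjusted p under 0.05, mean log2 CPM (library-scaled counts) of at least 3 and the same sign in every line compared. Some genes that meet this rule are not reported here. For each list, the count of members past the threshold over all genes is given, and beside it the count after adjustment over the list alone. A list score is the mean log2 CPM (prior count 2) over the list in a library. Scores were compared with two-sided exact permutation tests where an arm had fewer than 10 libraries and otherwise with 100000 permutations within line, for which 1e-05 is the smallest p possible; differences between line classes used permuted residuals of the additive model. Beside a score, k of n libraries counts the libraries of the first arm that lie on the stated side of the mean of the other arm. The 492 list tests were adjusted together, and another 768 tests by line were adjusted together.

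Alternatives fixed in advance were DESeq2 size factors in the same fit, no filter on low counts, the DESeq2 1.42.0 Wald test, a block term for the 3 pairs of neighbouring title numbers in a group, removal of libraries under 0.333 of the median depth of their set, limma 3.58.1 (trend) on the second table for 17 of the 41 comparisons, leaving out each library in turn where an arm had 5 or fewer, and for list scores the median over the list. Added after seeing the data were removal of libraries in which MT-RNR2, the mitochondrial 16S ribosomal RNA, took under 5 percent of counts (libraries that stand apart) and a term for ranges of 96 title numbers. Counts without the libraries that stand apart are given beside the counts with all libraries. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

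The tests were tested on simulated data made from the libraries of 3 comparisons with known changes planted and all other genes left in step. For K660N against GFP at DMSO (6 and 6 libraries, 12511 genes in step), edgeR recovered 26.8 percent of changes of log2 size 1 and 90.5 percent of size 2, with 1.75 percent of its calls false; DESeq2 recovered 54.6 and 93.7 percent with 16.0 percent false. For fulvestrant with FGF2 against fulvestrant in the FGFR2 lines (24 and 24 libraries, 13400 in step), edgeR recovered 94.0 and 100 percent with 5.45 percent false, and DESeq2 the same shares with 8.17 percent false. For the interaction of that treatment with FGFR1 against the control lines (13580 in step), edgeR recovered 53.0 and 98.0 percent with 6.79 percent false, and DESeq2 55.0 and 99.0 percent with 12.5 percent false.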

Results

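Each overexpressed gene was read at a high level in the line labelled with it. At DMSO, FGFR1, a receptor tyrosine kinase for FGF ligands, was at 8.48 ± 1.53 in the FGFR1 line on the scale log2(CPM + 1), as mean ± SD (n = 5), and at 2.92 ± 0.42 in the GFP line (n = 6). It was the 1 gene past the threshold between the lines (6.11 ± 0.58; 1 higher, 0 lower, 4 calls without the libraries that stand apart). FGFR2, the receptor bearing the mutations studied here, was at 3.96 ± 0.41 in the GFP line (n = 6). It was at 7.36 ± 1.31 (n = 6), 7.48 ± 1.17 (n = 5), 7.59 ± 1.40 (n = 6) and 9.17 ± 0.34 (n = 6) in the wild-type, M538I, N550K and K660N lines. FGF3, a secreted ligand of FGFR1 and FGFR2, was at 7.28 ± 0.88 in its line (n = 5), and in the GFP line 8 reads of FGF3 fell in 1 of 6 libraries. The large spread in the receptor lines came with low values in libraries that stand apart.

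**Figure D1:**
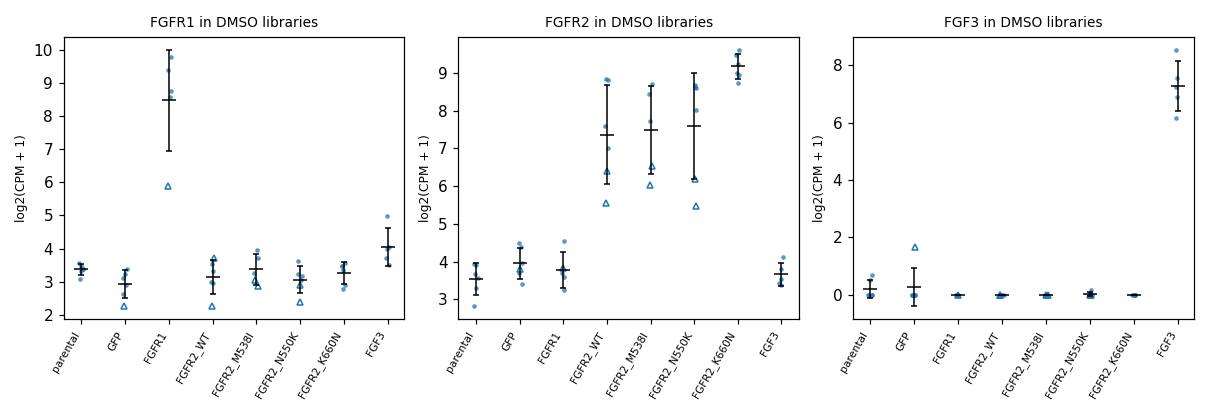
Expression of FGFR1, FGFR2 and FGF3 at DMSO in set 1, as log2(CPM + 1) on the vertical axes, with the 8 lines along the horizontal axes. Each point is 1 library, open triangles are libraries that stand apart, and bars give the mean and SD. FGFR1 averaged 8.48 in the FGFR1 line, FGFR2 between 7.36 and 9.17 in the FGFR2 lines, and FGF3 7.28 in the FGF3 line.

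**Figure D2:**
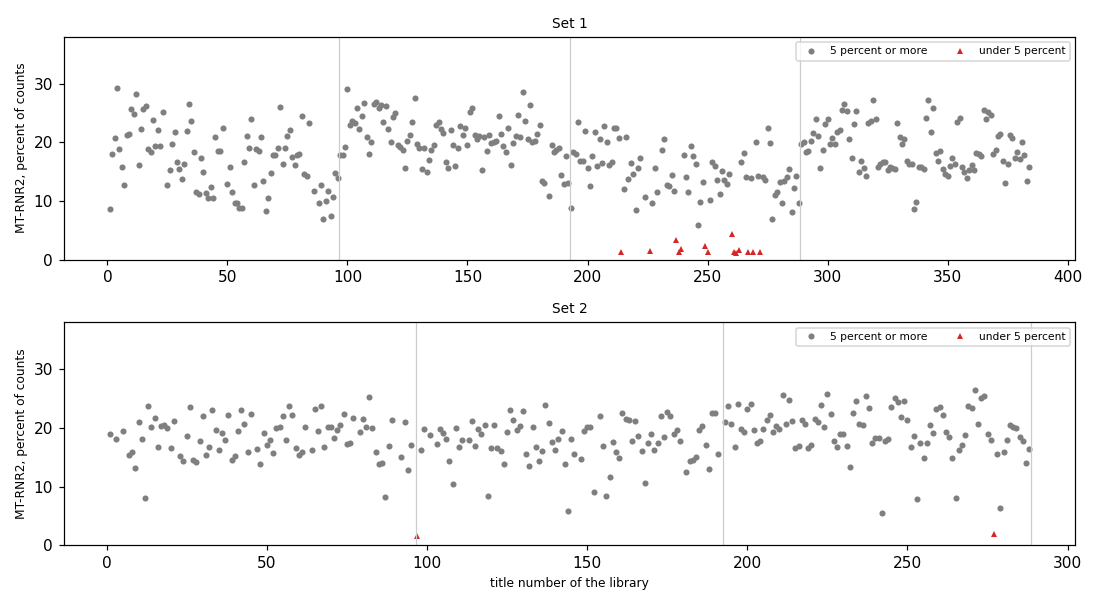
MT-RNR2 as a percent of all counts in each library (vertical axis) against the title number of the library (horizontal axis), for set 1 (upper panel) and set 2 (lower panel). Gray circles are libraries with 5 percent or more, red triangles the 16 libraries that stand apart, and vertical lines separate ranges of 96 title numbers. Of the 16, which had 1.09 to 4.43 percent, 14 lie in the third range of set 1.

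Without drug or ligand, few genes separated the wild-type FGFR2 line from GFP at the depth used here. FGFR2 itself was the 1 gene past the threshold (3.85 ± 0.52; n = 6 and 6; 1 higher, 0 lower, 3 calls without the libraries that stand apart). Calls were 16 with DESeq2, 15 with the title-number block, 24 without a filter on low counts and 0 with limma, and 7.83 percent of 12383 genes had unadjusted p below 0.05. The parental and GFP lines, both controls, differed at 0 genes by edgeR (n = 6 and 6; 1898 genes at unadjusted p below 0.05), 0 by limma and 1.32 percent of 12417 by DESeq2. The count was 11 without the 1 GFP library that stands apart. In the M538I line, FGFR2 (3.87 ± 0.47) and the interferon-induced gene IFI27 (6.89 ± 0.83) were higher and 0 genes were lower (n = 5 and 6). The feedback phosphatase DUSP6 was at 2.32 ± 0.38 (adjusted p = 0.0532), short of the threshold. Leaving out GFP replicate 6, a library that stands apart, raised the count from 2 to 51 calls. Leaving out all 3 libraries that stand apart raised it to 1.76 percent of 12585 genes, limma gave 2 calls and DESeq2 1.04 percent. The interferon response score was higher by 0.87 ± 0.32 (4 of 5 libraries, exact permutation p = 0.0152, adjusted p = 0.0439). Without the libraries that stand apart it was at 0.73 ± 0.37 (adjusted p = 0.162), but with 3 and 5 libraries left no list score could pass. Against the wild-type receptor line, 0 genes passed for M538I with edgeR, DESeq2 or limma, 8 with the title-number block and 2 without a filter on low counts (n = 5 and 6; 1.02 percent of 12472 genes at unadjusted p below 0.05 in edgeR).

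The N550K and K660N lines had higher interferon and MAPK output scores at DMSO. In N550K, DUSP6 was higher by 4.01 ± 0.41, FGFR2 by 4.03 ± 0.53, the interferon genes IFI27 by 9.28 ± 1.05 and IFIT3 by 6.34 ± 0.69, and ANXA1, a phospholipid-binding protein linked to basal cells, by 3.57 ± 0.50. Lower were PGR, the progesterone receptor and a classical estrogen receptor target (−2.64 ± 0.32), ESR1, the estrogen receptor itself (−1.64 ± 0.25), SCUBE2 (−3.26 ± 0.38) and KRT4 (−3.33 ± 0.51). Of 12579 genes tested 0.954 percent were higher and 0.644 percent lower (n = 6 and 6; 8.16 percent called without the 3 libraries that stand apart). Of 11 MAPK output genes tested, 4 were higher and 1 lower (adjusted over the list alone, 7 and 2). The score of that list was higher by 1.00 ± 0.19 (6 of 6 libraries, exact permutation p = 0.00433, adjusted p = 0.016), but did not pass on the second table (0.57). Of 17 interferon response genes 7 were higher and 0 lower (11 and 0). The interferon score was higher by 2.02 ± 0.19 (6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845). Lower was the estrogen receptor target score (−0.63 ± 0.18, 6 of 6 libraries, exact permutation p = 0.00649, adjusted p = 0.0206), with 3 of 23 members lower over all genes and 5 over the list alone. It did not pass with the list median (−0.40) or on the second table (−0.38). The G2/M and mitosis score was higher (0.40 ± 0.11, 6 of 6 libraries, exact permutation p = 0.00649, adjusted p = 0.0206) although 0 of its members passed over all genes.

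In K660N, IFIT3 (7.84 ± 0.44), IFI27 (7.30 ± 0.46), FGFR2 (5.22 ± 0.29), DUSP6 (3.23 ± 0.30), the stress cytokine GDF15 (2.99 ± 0.43) and the cell cycle inhibitor CDKN1A (1.26 ± 0.20) were higher than in GFP. PGR (−1.70 ± 0.24) and SCUBE2 (−1.96 ± 0.30) were lower. Of 12682 genes tested 0.923 percent were higher and 0.591 percent lower (n = 6 and 6; 3.30 percent called without the GFP library that stands apart). Of the calls 60.9 percent were higher, against 26.2 percent without a filter on low counts and 84.7 percent with limma. Interferon response genes passed in 12 of 19 (15 over the list alone), all of them higher, and MAPK output genes split into 4 higher and 1 lower of 12 (6 and 2; score 0.67 ± 0.16, adjusted p = 0.0206). The G1/S and replication score was higher by 0.47 ± 0.16 (6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845), and the estrogen receptor target score lower (−0.35 ± 0.12, 6 of 6 libraries, exact permutation p = 0.0152, adjusted p = 0.0439). That score did not pass with the list median (−0.24) or on the second table (−0.017).

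Against wild-type FGFR2, N550K kept higher DUSP6 (3.03 ± 0.41), DUSP4 (2.21 ± 0.30), IFI27 (5.46 ± 1.10) and IFI6 (3.25 ± 0.52). Lower were PGR (−2.39 ± 0.38) and SCUBE2 (−3.11 ± 0.38). That made 38 genes higher and 19 lower (n = 6 and 6; 2.91 percent of 12399 called without the 4 libraries that stand apart). With all libraries 4 of 11 MAPK output genes were higher (6 over the list alone) and 4 of 17 interferon genes (8). K660N against wild type is read without the libraries that stand apart, since 2 were in the wild-type arm and 0 in the other. That left 1.92 percent of 12544 genes higher and 2.47 percent lower (with all 6 and 6 libraries 6.52 and 9.73 percent). With all libraries 40.1 percent of the calls were higher, against 89 percent with limma on the second table. Higher in that reading were MX1 (2.70 ± 0.28), IFI44L (4.30 ± 0.76), DUSP6 (1.92 ± 0.25) and CDKN1A (0.91 ± 0.19). PGR was lower (−1.74 ± 0.25), and the mitochondrial gene MT-CO2 moved from −1.90 ± 0.55 with all libraries to −0.43 ± 0.23 (adjusted p = 0.272) without them. Interferon genes passed in 18 of 19 with all libraries and in 14 without those that stand apart, and G1/S genes in 9 and 5 of 23.

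The FGF3 line differed from GFP in ERK feedback, basal and estrogen-regulated genes. Besides FGF3 (9.74 ± 0.91), the basal keratins KRT5 (7.34 ± 0.65) and KRT17 (6.33 ± 0.45), the protease PLAU (6.18 ± 0.88), the chemokine receptor CXCR4 (4.38 ± 0.42) and the ERK feedback genes SPRY4 (4.56 ± 0.64), ETV4 (3.88 ± 0.75) and DUSP6 (3.73 ± 0.35) were higher. So was the receptor FGFR4 (2.10 ± 0.39). PGR (−3.95 ± 0.35), ESR1 (−1.51 ± 0.25), SERPINA6 (−3.09 ± 0.28) and the ephrin receptor EPHA4 (−4.07 ± 0.59) were lower. Of MAPK output genes 7 of 14 were higher and 1 lower, and of basal or mesenchymal genes 4 of 9 were higher (5 over the list alone; score 1.35 ± 0.18, 5 of 5 libraries, exact permutation p = 0.00216, adjusted p = 0.00845). The estrogen receptor target score was lower (−0.89 ± 0.20, 5 of 5 libraries, exact permutation p = 0.00216, adjusted p = 0.00845), but did not pass on the second table (−0.24). Of the interferon list, IFI27 (3.56 ± 0.63) and IFI6 (1.53 ± 0.31) were higher while the score was at −0.13 ± 0.09 (adjusted p = 0.34). Of 3 measured genes of other cell types (fibroblast, blood, endothelium) 0 passed. Their score was at 0.13 ± 0.16 (adjusted p = 0.656), and was higher without the libraries that stand apart (0.28 ± 0.08, adjusted p = 0.0476). In all 393 genes were higher and 477 lower (n = 5 and 6), so 45.2 percent of the calls were higher, against 70.6 percent with limma and 23.5 percent without a filter on low counts. This count of 870 is unstable: it was 2305 without GFP replicate 6, which stands apart, and 470 without GFP replicate 4. It was 422, 440 and 512 without FGF3 replicates 2, 4 and 5, and 15 without the 4 FGF3 libraries of low depth.

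Added FGF2, a ligand of all 4 FGF receptors, raised ERK feedback and cell cycle expression even in the control lines. DUSP6 rose by 2.22 ± 0.23, ANXA1 by 1.64 ± 0.35 and the proliferation marker MKI67 by 1.02 ± 0.11. FGF12 (−1.39 ± 0.15), KRT4 (−1.18 ± 0.15) and the estrogen-regulated chemokine CXCL12 (−1.03 ± 0.15) fell. Of 12989 genes tested 3.70 percent were higher and 2.42 percent lower (n = 12 and 12; 9.70 percent called without the 1 library that stands apart). Of 21 G2/M genes 20 rose (score 1.07 ± 0.09, 12 of 12 libraries, permutation p = 2e-05, adjusted p = 0.000147) and of 23 G1/S genes 5 (6 over the list alone). MAPK output genes split into 4 that rose and 1 that fell of 13, and 4 of 14 luminal identity genes fell.

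In the FGFR1 line the ETS factor ETV4, an ERK target, rose by 7.63 ± 0.55, SPRY4 by 6.18 ± 0.55, the adaptor LAT2 by 4.71 ± 0.40, DUSP6 by 4.10 ± 0.38 and the squamous gene IVL by 3.70 ± 0.27. FGF12 (−4.06 ± 0.39), KRT4 (−3.58 ± 0.27), PGR (−1.86 ± 0.23) and ESR1 (−1.12 ± 0.19) fell. MAPK output genes rose in 16 of 20 with 1 falling (score 1.73 ± 0.10, 6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845). G2/M genes rose in 17 of 21 and G1/S genes in 10 of 23 (13 over the list alone). Of 12583 genes tested 14.4 percent were higher and 17.3 percent lower (n = 6 and 5; 34.2 percent called without the DMSO library that stands apart). That library carried several large values: ISG15, an interferon-induced modifier, went from −4.02 ± 1.17 to −0.33 ± 0.55 (adjusted p = 0.67) without it, and MT-CO2 from −3.14 ± 0.74 to −1.17 ± 0.18. In the 4 FGFR2 lines together, SPRY4 (3.17 ± 0.32), ETV4 (3.01 ± 0.28), the AP-1 gene FOSL1 (2.60 ± 0.35), IVL (2.62 ± 0.24) and DUSP6 (2.26 ± 0.18) rose. ESR1 (−0.86 ± 0.10), PGR (−1.14 ± 0.16) and the insulin receptor INSR (−1.27 ± 0.20) fell. MAPK output genes rose in 16 of 21 (1 fell) and ribosome biogenesis genes in 6 of 13 (2 fell; score 0.21 ± 0.02, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). Of 13591 genes tested 21.4 percent were higher and 26.2 percent lower (n = 24 and 23), against 16.5 and 13.7 percent without the 6 DMSO libraries that stand apart. With the range term 24.5 percent were called in all, and FGFR2 went from 0.83 to −0.0079.

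**Figure D3:**
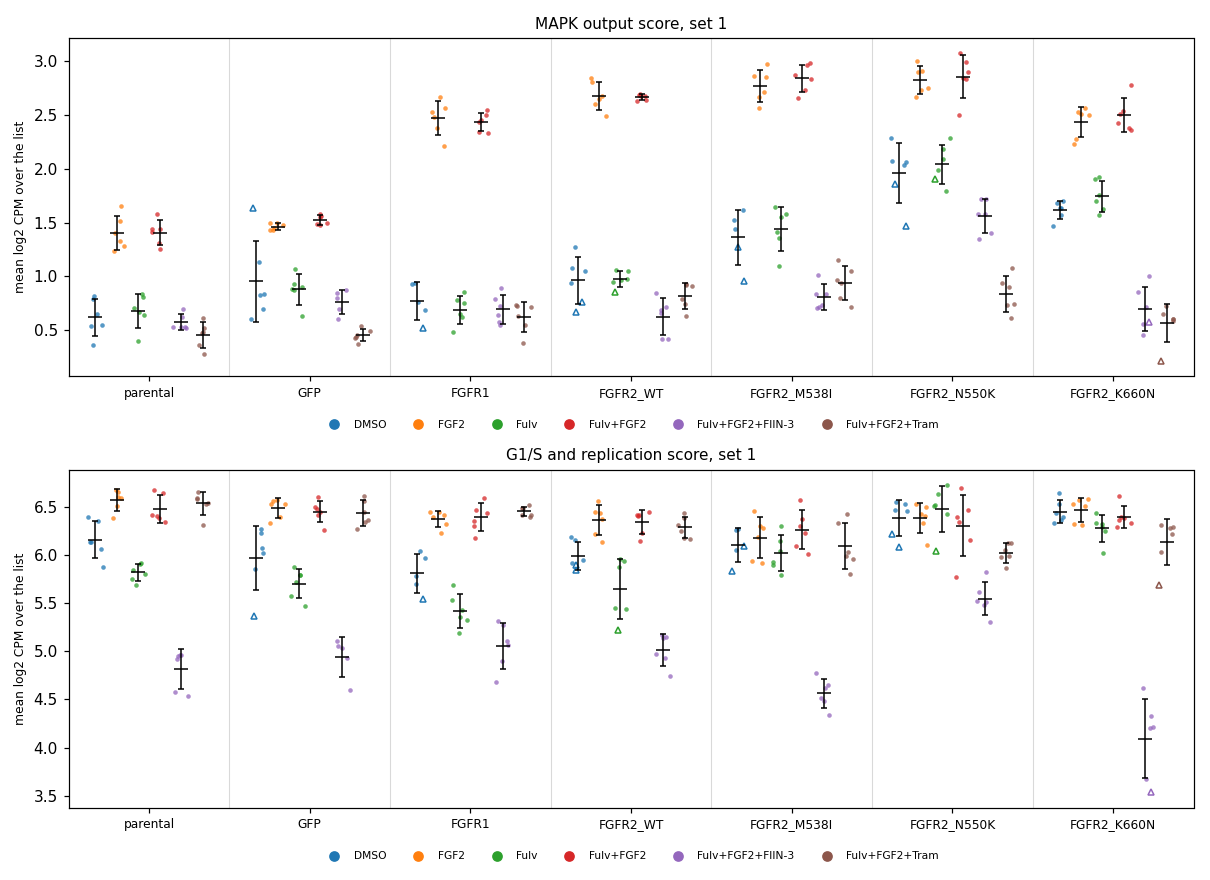
MAPK output score (upper panel) and G1/S and replication score (lower panel), each the mean log2 CPM over its list on the vertical axis, for 7 lines of set 1 along the horizontal axis and 6 treatments by color. Each point is 1 library, open triangles are libraries that stand apart, and bars give the mean and SD. With fulvestrant and FGF2, FIIN-3 lowered both scores in the FGFR2 lines (by 1.75 and 1.48), whereas trametinib lowered the MAPK output score by 1.91 and the G1/S score by 0.16.

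Fulvestrant, which degrades the estrogen receptor, lowered estrogen-induced genes in the control lines. CXCL12 (−3.43 ± 0.17), the secreted glycoprotein gene OLFM1 (−3.05 ± 0.21), the scaffold gene PDZK1 (−2.00 ± 0.28), SERPINA6 (−1.68 ± 0.17), MYB (−1.71 ± 0.37), GREB1 (−0.96 ± 0.16) and MYC (−0.85 ± 0.16) fell. EGLN3 (1.12 ± 0.14), the atrophy-linked ubiquitin ligase gene FBXO32 (1.05 ± 0.13), TMPRSS2 (1.03 ± 0.19) and the growth factor receptor ERBB2 (0.64 ± 0.16) rose. Of 25 estrogen receptor targets 11 fell and 0 rose (15 fell over the list alone; score −0.69 ± 0.06, 12 of 12 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). The G1/S score fell (−0.27 ± 0.10, 12 of 12 libraries, permutation p = 0.00983, adjusted p = 0.0295), with 1 member past the threshold over all genes and 11 over the list alone, and so did the ribosome biogenesis score (−0.28 ± 0.06, adjusted p = 0.00186). Of 13101 genes tested 0.572 percent were higher and 0.977 percent lower (n = 12 and 12; 2.79 percent called without the 1 library that stands apart).

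In the FGFR1 line TFF1 (−3.43 ± 0.54), OLFM1 (−3.00 ± 0.27), CXCL12 (−2.81 ± 0.28) and SIAH2 (−1.40 ± 0.24) fell. That made 3 of 23 list members lower (8 over the list alone; score −0.75 ± 0.17, 6 of 6 libraries, exact permutation p = 0.00649, adjusted p = 0.0206). The score did not pass with the list median (−0.72) or on the second table (−0.46). The count of 10 lower and 0 higher genes (n = 6 and 5) depended on single libraries. It was 26 without DMSO replicate 3, which stands apart. Without DMSO replicates 1, 4 or 5 it was 4, 4 and 5, and without fulvestrant replicates 1, 2, 3, 4 or 6 it was 6, 4, 6, 5 and 4. In the FGFR2 lines CXCL12 (−2.21 ± 0.13), OLFM1 (−1.93 ± 0.18), SERPINA6 (−1.82 ± 0.18), STC2 (−1.32 ± 0.11), MYC (−1.10 ± 0.17) and GREB1 (−0.84 ± 0.16) fell, and BTG2 (0.69 ± 0.14) and EMP1 (0.78 ± 0.19) rose. Targets of the estrogen receptor fell in 10 of 24 (12 over the list alone; score −0.42 ± 0.07, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). By line, M538I (−0.31 ± 0.13, exact permutation, adjusted p = 0.0909) and N550K (−0.28 ± 0.17, adjusted p = 0.249) did not pass, and neither did the pooled score on the second table (−0.23). Of 13669 genes tested 1.08 percent were higher and 1.86 percent lower (n = 24 and 23; 4.11 percent called without the 8 libraries that stand apart). With the title-number block 16.1 percent were called, of which 50.5 percent were higher, against 36.8 percent as reported. In the FGF3 line 0 genes passed with edgeR (n = 4 and 5; 410 at unadjusted p below 0.05), 3 with DESeq2, 0 with limma, 5 with the title-number block and 53 without a filter on low counts. Leaving out fulvestrant replicate 3 gave 1 call. There the estrogen receptor target score was at −0.03 ± 0.21 (exact permutation p = 0.921, adjusted p = 0.968), KRT5 was at 2.28 ± 0.59 (adjusted p = 0.995) and STC2 at −0.68 ± 0.12 (adjusted p = 0.169).

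**Figure D4:**
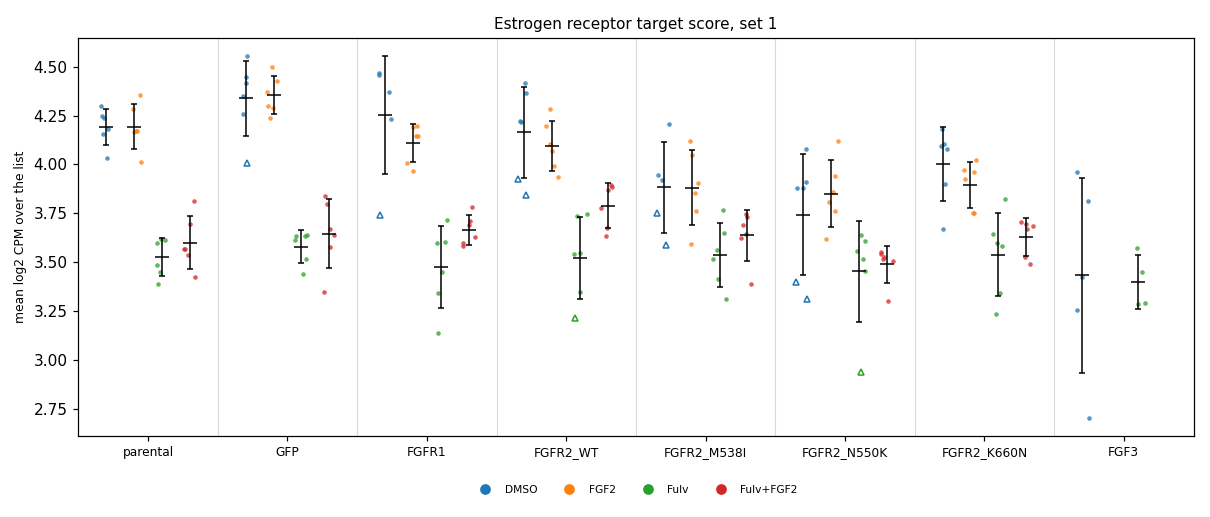
Estrogen receptor target score, the mean log2 CPM over the list (vertical axis), for 8 lines of set 1 (horizontal axis) and 4 treatments by color, where the FGF3 line has DMSO and fulvestrant only. Each point is 1 library, open triangles are libraries that stand apart, and bars give the mean and SD. Fulvestrant lowered the score by 0.69 in the control lines and by 0.42 in the FGFR2 lines.

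Interaction tests compared the fulvestrant response between lines. In the FGFR2 lines CXCL12 fell less than in the control lines (interaction 1.24 ± 0.22), the 1 gene past the threshold (2 without the libraries that stand apart, 0 with limma and 22 without a filter on low counts). The score of estrogen receptor targets fell less by 0.28 ± 0.11 (permutation p = 0.00472, adjusted p = 0.016), but did not pass with the list median (0.19) or on the second table (0.27). In the FGF3 line CXCL12 again gave the 1 call (interaction 3.17 ± 0.31), and the score differed by 0.68 ± 0.18 (permutation p = 0.00738, adjusted p = 0.0231). That difference did not pass with the list median (0.51), on the second table (0.49) or without libraries of low depth (0.73). The mean score of the FGF3 line was already 3.43 at DMSO and was 3.40 with fulvestrant. The count there was 4 without GFP DMSO replicate 6 and 2 without FGF3 fulvestrant replicate 3. It was 19 with limma, 15 without a filter on low counts, 11 with DESeq2 and 6 with the title-number block. The G1/S score (0.46 ± 0.15, permutation p = 0.00283, adjusted p = 0.011) and the ribosome biogenesis score (0.34 ± 0.09, permutation p = 0.00114, adjusted p = 0.0063) also differed from the control lines. In the FGF3 line itself they were at 0.17 ± 0.06 and 0.04 ± 0.08 (exact permutation, adjusted p = 0.111 and 0.76). For the FGFR1 line 0 genes passed with edgeR (1.38 percent of 13900 at unadjusted p below 0.05), 0 with DESeq2 and 0 with limma. The score difference was −0.06 ± 0.14 (permutation p = 0.759, adjusted p = 0.874).

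FGF2 given on top of fulvestrant raised cell cycle gene expression. By line, the estrogen receptor target score moved by 0.04 to 0.24, and 0 of 7 lines passed. In the control lines DUSP6 (2.45 ± 0.16), SPRY4 (3.79 ± 0.51), DUSP4 (1.66 ± 0.10), the cohesion gene ESCO2 (1.62 ± 0.20) and cyclin D1, CCND1 (0.68 ± 0.11) rose. FGF12 (−1.49 ± 0.13), SCUBE2 (−1.18 ± 0.15) and DDIT4 (−1.12 ± 0.11) fell. Of the G1/S list 21 of 23 rose (score 0.69 ± 0.06, 12 of 12 libraries, permutation p = 1e-05, adjusted p = 9.11e-05), of the G2/M list 21 of 21, and of MAPK output genes 7 of 15 rose and 1 fell. The estrogen receptor target score was at 0.06 ± 0.05 (permutation p = 0.283, adjusted p = 0.479), with 2 members of 23 higher and 1 lower. Of 13083 genes tested 7.02 percent were higher and 4.95 percent lower (n = 12 and 12).

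The same addition in the FGFR1 line raised ETV4 (7.78 ± 0.51), SPRY4 (6.93 ± 0.56), DUSP6 (4.58 ± 0.24), IVL (4.51 ± 0.22) and CCND1 (1.20 ± 0.14). Lowered were KRT4 (−3.65 ± 0.29), ESR1 (−1.22 ± 0.17), PGR (−1.57 ± 0.29) and the receptors EGFR (−1.52 ± 0.29) and ERBB4 (−1.37 ± 0.34). G1/S genes rose in 19 of 23 (score 0.94 ± 0.10, 6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845) and G2/M genes in 21 of 21. Of 12463 genes tested 12.7 percent were higher and 14 percent lower (n = 6 and 6). With FGFR2, FOSL1 (3.34 ± 0.39), SPRY4 (3.03 ± 0.31), ETV4 (2.96 ± 0.27), IVL (2.60 ± 0.21) and GDF15 (2.41 ± 0.23) rose. ESR1 (−0.82 ± 0.10), PGR (−0.83 ± 0.14) and BCAS1 (−1.45 ± 0.13) fell. MAPK output genes rose in 17 of 21 (score 1.17 ± 0.07, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05), G1/S genes in 7 of 23, G2/M genes in 20 of 21 and ribosome biogenesis genes in 8 of 13, while 7 of 14 cholesterol synthesis genes fell and 1 rose. Of 13494 genes tested 16.9 percent were higher and 20.3 percent lower (n = 24 and 24; 38.3 percent called without the 2 libraries that stand apart).

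Interaction tests showed which parts of the FGF2 response under fulvestrant exceeded that of the control lines. With FGFR1, ETV4 (5.44 ± 1.16), IVL (3.28 ± 0.25), DUSP6 (2.15 ± 0.27), AREG (1.92 ± 0.33) and KRT18 (1.60 ± 0.20) rose more. KRT4 (−2.54 ± 0.30), FGF12 (−2.34 ± 0.28) and EGFR (−1.39 ± 0.29) fell more. The response was higher in 2.03 and lower in 2.77 percent of 13777 genes. The MAPK output score rose more by 1.07 ± 0.09 (permutation p = 1e-05, adjusted p = 9.11e-05), with 6 members of 20 higher and 1 lower (11 and 1 over the list alone). In the FGFR2 lines GPRC5A (1.95 ± 0.19), CAPN8 (2.28 ± 0.44), GDF15 (2.00 ± 0.39), KRT8 (1.38 ± 0.16) and KRT18 (1.28 ± 0.19) rose more, and the replication genes PCNA (−0.74 ± 0.16) and TYMS (−0.67 ± 0.14) less. Of 14113 genes 1.46 percent had a higher and 1.77 percent a lower response (5.24 percent called without the 2 libraries that stand apart). The G1/S score rose less in the pooled FGFR2 lines (interaction −0.46 ± 0.11, permutation p = 3e-05, adjusted p = 0.000202), with 8 of 23 members lower (18 over the list alone). By line, its mean went from 5.65 to 6.35 in wild type, against 5.82 to 6.48 in parental and 5.70 to 6.45 in GFP. It went from 6.02 to 6.26 in M538I, 6.28 to 6.40 in K660N and 6.48 to 6.30 in N550K, lines with higher means under fulvestrant alone. The response of the luminal identity score was higher than in the control lines (interaction 0.42 ± 0.06, permutation p = 1e-05, adjusted p = 9.11e-05). For MAPK output the score difference was positive (0.49 ± 0.11, permutation p = 3e-05, adjusted p = 0.000202) while the median gene of the list was at −0.10 and 1 of 21 members passed, so the list's direction rests on the measure used. By line the score rose by 1.69 ± 0.04 in wild type and 1.41 ± 0.09 in M538I, but by 0.83 ± 0.10 in N550K and 0.75 ± 0.09 in K660N, near the 0.74 ± 0.08 and 0.67 ± 0.06 of the control lines.

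FIIN-3 lowered ERK feedback and cell cycle expression in all 3 line classes. In the control lines SPRY4 (−4.62 ± 0.52), ACOX2 (−3.63 ± 0.35), DUSP6 (−2.73 ± 0.16), MKI67 (−2.06 ± 0.13) and CCND1 (−1.11 ± 0.10) fell and the arrestin-related gene ARRDC3 (1.80 ± 0.19), ELF3 (1.18 ± 0.08), PGR (0.88 ± 0.17) and ESR1 (0.46 ± 0.08) rose. Falls were seen in 23 of 23 G1/S genes, 21 of 21 G2/M genes and 6 of 13 MAPK output genes. Of 12950 genes tested 10.9 percent were higher and 13.8 percent lower (n = 11 and 12). In the FGFR1 line SPRY4 (−8.66 ± 0.64), LAT2 (−6.12 ± 0.40), ETV4 (−5.05 ± 0.49) and DUSP6 (−4.49 ± 0.21) fell. KRT4 (3.50 ± 0.28), FGF12 (3.28 ± 0.27), ESR1 (1.45 ± 0.14) and PGR (1.63 ± 0.27) rose, with 22 of 23 G1/S genes lower and 13 of 16 MAPK output genes lower and 1 higher. Of 12236 genes tested 14.7 percent were higher and 15.1 percent lower (n = 6 and 6).

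In the FGFR2 lines FIIN-3 lowered FOSL1 (−5.62 ± 0.39), SPRY4 (−5.30 ± 0.30), ETV4 (−4.13 ± 0.25), DUSP6 (−3.98 ± 0.24) and also IFIT3 (−4.63 ± 0.32). It raised ESR1 (1.21 ± 0.09), ERBB4 (1.23 ± 0.18) and INSR (1.10 ± 0.12). MAPK output genes fell in 17 of 21 (2 rose; score −1.75 ± 0.06, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). In N550K the score fell least, by 1.26 ± 0.10, and stayed at 1.56 ± 0.16 (mean ± SD), against means of 0.63 to 0.81 in the other 3 FGFR2 lines. This held with added FGF2 only. The N550K mean was 1.78 with FIIN-3 and FGF2, but 0.65 with FIIN-3 alone and 0.69 with fulvestrant and FIIN-3. G1/S genes fell in 22 of 23 (score −1.48 ± 0.11, adjusted p = 9.11e-05), interferon genes in 11 of 18 (2 rose; score −0.90 ± 0.13, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05) and ribosome biogenesis genes in 10 of 13. Estrogen receptor targets split into 4 that rose and 12 that fell of 22. The stress and unfolded protein response had 4 members higher and 4 lower of 13, with a score of −0.17 ± 0.07 (adjusted p = 0.0272) and a median gene at 0.05, so the measures differ in sign. Of 13309 genes tested 30.3 percent were higher and 28.6 percent lower (n = 24 and 24; 61.1 percent called without the 1 library that stands apart).

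Trametinib, which blocks MEK downstream of the receptor, also lowered ERK feedback but left most G1/S genes expressed. In the control lines SPRY4 (−4.87 ± 0.51), DUSP6 (−3.95 ± 0.19) and DUSP4 (−3.66 ± 0.14) fell, and the heat-shock protein gene HSPB1 (2.68 ± 0.10), VTCN1 (1.78 ± 0.07), the cyclin-kinase inhibitor CDKN2B (1.60 ± 0.13) and KRT8 (1.34 ± 0.10) rose. G1/S genes split into 1 that rose and 3 that fell of 23, against 18 of 21 G2/M genes that fell. Interferon genes fell in 9 of 14 (score −0.53 ± 0.10, 11 of 12 libraries, permutation p = 0.00013, adjusted p = 0.00082), and ribosome biogenesis genes rose in 10 of 13. Of 12898 genes tested 11.8 percent were higher and 16 percent lower (n = 12 and 12). In the FGFR1 line SPRY4 (−7.09 ± 0.53), ETV4 (−5.35 ± 0.48) and DUSP6 (−5.27 ± 0.20) fell. HSPB1 (2.11 ± 0.11), PGR (1.28 ± 0.22) and ESR1 (0.73 ± 0.12) rose. Of G1/S genes 0 of 23 passed, and 9 of 14 cholesterol synthesis genes rose. Of 12323 genes tested 5.48 percent were higher and 5.83 percent lower (n = 6 and 6). The range term gave 6.56 percent called in all. Interferon genes such as IFIT1 (−5.72 ± 1.48) fell in 4 of 15, but the score was at −0.75 ± 0.65 (exact permutation p = 0.232, adjusted p = 0.406), as 1 library with fulvestrant and FGF2 had a score of 5.81 and the other 5 scored at most 2.57.

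Trametinib in the FGFR2 lines lowered ETV4 (−5.75 ± 0.24), SPRY4 (−5.75 ± 0.31), DUSP6 (−5.18 ± 0.12) and the early-response gene EGR1 (−4.94 ± 0.38), with 20 of 21 MAPK output genes lower (score −1.91 ± 0.04, 24 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). It raised genes of interferon and antigen presentation: IDO1, a tryptophan-degrading enzyme induced by interferon (3.50 ± 0.59), IFIT2 (2.41 ± 0.36), and the class II genes HLA-DPA1 (2.48 ± 0.38) and HLA-DRA (2.37 ± 0.39). It also raised the acute-phase gene LBP (3.14 ± 0.62) and the proapoptotic gene BIK (2.56 ± 0.18). Interferon response genes rose in 18 of 19 (score 1.23 ± 0.17, 23 of 24 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). G1/S genes fell in 5 of 23 (score −0.16 ± 0.05, adjusted p = 0.016) and G2/M genes in 21 of 21. Stress genes rose in 7 of 14, with ATF3 at 1.44 ± 0.13 and DDIT4 at 1.39 ± 0.14, and 2 fell. Estrogen receptor targets had 3 higher and 6 lower of 22; the mean score was at −0.22 ± 0.05 (adjusted p = 0.000202), but the median gene was at −0.02 and the score taken as the median over the list at 0.05. Of 13283 genes tested 15.3 percent were higher and 13.7 percent lower (n = 24 and 24; 33.6 percent called without the 1 library that stands apart).

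**Figure D5:**
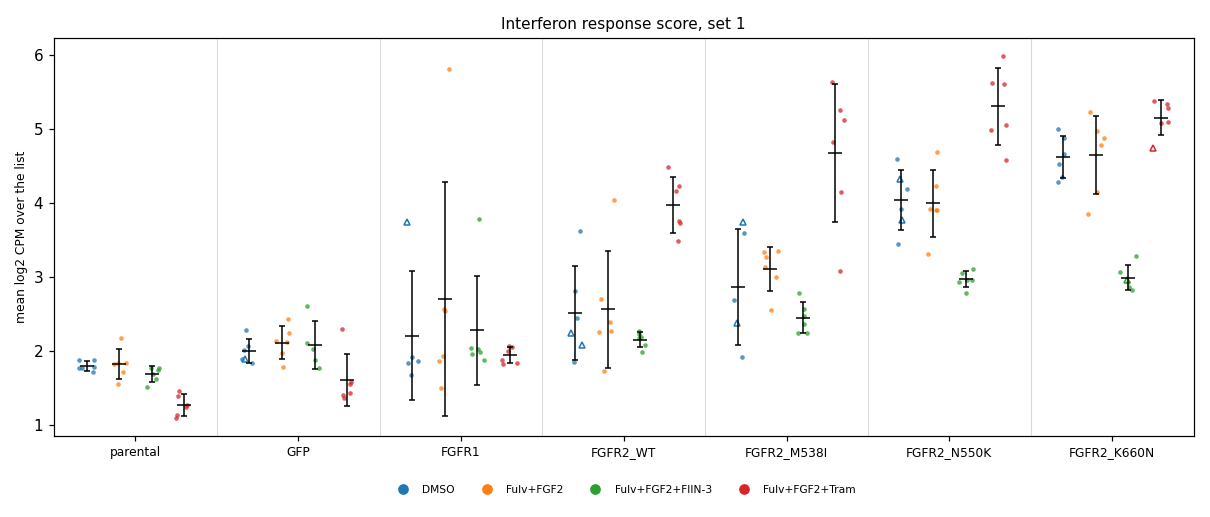
Interferon response score, the mean log2 CPM over the list (vertical axis), for 7 lines of set 1 (horizontal axis) and 4 treatments by color. Each point is 1 library, open triangles are libraries that stand apart, and bars give the mean and SD. Trametinib raised the score by 1.23 in the FGFR2 lines and lowered it by 0.53 in the control lines, and 1 FGFR1 library with fulvestrant and FGF2 lay at 5.81.

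Compared directly in the 5 receptor lines, trametinib left higher levels than FIIN-3 of IDO1 (9.61 ± 0.72), LBP (6.57 ± 0.58), IFIT3 (6.13 ± 0.37), the transglutaminase TGM2 (5.33 ± 0.49), MKI67 (1.41 ± 0.11) and CDKN1A (1.37 ± 0.09). Lower was ESR1 (−0.64 ± 0.07). G1/S genes were higher in 22 of 23 (score 1.32 ± 0.08, 30 of 30 libraries, permutation p = 1e-05, adjusted p = 9.11e-05). So were G2/M genes in 21 of 21, ribosome biogenesis genes in 11 of 13 and interferon genes in 15 of 19. Interferon scores were higher by 1.78 to 2.34 with FGFR2 but at −0.38 ± 0.31 in FGFR1. MAPK output genes split into 3 higher and 5 lower of 11 with a score of −0.13 ± 0.06 (permutation p = 0.0245, adjusted p = 0.0647). In N550K the MAPK output score was lower (−0.71 ± 0.09, exact permutation p = 0.00216, adjusted p = 0.00918), and 0 of the other 4 lines passed. The pooled score passed with DESeq2 size factors (−0.15). Receptors and adaptors had 1 higher and 4 lower of 10 (score −0.24 ± 0.06, permutation p = 0.00033, adjusted p = 0.00193). Of 13455 genes tested 29.4 percent were higher and 27.5 percent lower (n = 30 and 30; 61.6 percent called without the 2 libraries that stand apart).

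Palbociclib, an inhibitor of CDK4 and CDK6, added to fulvestrant and FGF2 in 7 lines, lowered the mitotic kinase AURKB (−6.31 ± 0.16), the ribonucleotide reductase RRM2 (−6.29 ± 0.16), MKI67 (−5.16 ± 0.14) and E2F1 (−3.37 ± 0.10). DDIT4 (1.96 ± 0.10), C1orf64 (1.36 ± 0.10), DUSP6 (0.88 ± 0.05), CCND1 (0.84 ± 0.06) and PGR (0.69 ± 0.10) rose. G1/S genes fell in 23 of 23 (score −3.07 ± 0.05, 41 of 41 libraries, permutation p = 1e-05, adjusted p = 9.11e-05) and G2/M genes in 21 of 21 (score −4.04 ± 0.08, adjusted p = 9.11e-05), while 11 of 14 luminal identity genes rose. For estrogen receptor targets 5 rose and 5 fell of 24, and the score (−0.14 ± 0.03, adjusted p = 0.000511) and the median gene (0.03) differed in sign. Of 13898 genes tested 26.8 percent were higher and 22.3 percent lower (n = 41 and 42; 50.4 percent called without the 2 libraries that stand apart).

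In the FGF3 line, where the ligand is made by the cells, FIIN-3 alone lowered SPRY4 (−4.05 ± 0.53), DUSP6 (−3.59 ± 0.34) and the replication factor CDC45 (−2.50 ± 0.20). Raised were KRT4 (3.33 ± 0.48) and ESR1 (0.90 ± 0.20). G1/S genes fell in 21 of 22 (score −1.69 ± 0.11, 6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845) and MAPK output genes in 4 of 9. Of 10169 genes tested 4.39 percent were higher and 6.03 percent lower (n = 6 and 5; 1.49 percent called without libraries of low depth). Added to fulvestrant, FIIN-3 lowered TGM2 (−5.65 ± 0.49), SPRY4 (−5.56 ± 0.65), DUSP6 (−4.09 ± 0.38), the DNA methylation factor UHRF1 (−3.33 ± 0.28) and KRT5 (−2.80 ± 0.80), with 22 of 22 G1/S genes and 3 of 10 basal or mesenchymal genes lower. Of 11171 genes tested 5.34 percent were higher and 7.79 percent lower (n = 6 and 4). Trametinib added to fulvestrant lowered SPRY4 (−6.89 ± 0.52), ETV4 (−6.40 ± 0.73), DUSP6 (−5.90 ± 0.35), KRT5 (−3.75 ± 0.80) and CXCR4 (−3.66 ± 0.26). Raised were HSPB1 (2.89 ± 0.17) and VTCN1 (2.53 ± 0.16), with 13 of 23 G1/S genes lower (19 over the list alone). Of 12206 genes tested 2.99 percent were higher and 4.44 percent lower (n = 6 and 4). Palbociclib against the untreated group of set 2 lowered ESCO2 (−6.84 ± 0.53), RRM2 (−5.63 ± 0.31), MKI67 (−5.56 ± 0.40) and the antiviral gene OAS3 (−2.33 ± 0.21). Raised were JUNB (1.99 ± 0.40), DDIT4 (1.61 ± 0.32) and CCND1 (1.07 ± 0.22). G1/S genes fell in 21 of 22 and G2/M genes in 21 of 21 (score −3.68 ± 0.12, 6 of 6 libraries, exact permutation p = 0.00216, adjusted p = 0.00845). Of 10741 genes tested 1.73 percent were higher and 4.80 percent lower (n = 6 and 6; 14.8 percent called without the 1 library that stands apart).

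Under palbociclib alone, in set 2, 1 of 15 G1/S genes rose with FGF2 in the control lines, and 0 of 19 G2/M genes passed. ERK targets responded, with DUSP6 (3.09 ± 0.25), DUSP4 (1.94 ± 0.16), IVL (1.96 ± 0.15) and CCND1 (1.16 ± 0.12) higher and STC1 (−2.19 ± 0.34) and SERPINA6, a corticosteroid-binding globulin (−1.36 ± 0.15), lower. Of 11180 genes tested 0.778 percent were higher and 0.331 percent lower (n = 9 and 11; 3.72 percent called without the 1 library that stands apart). Of the calls 70.2 percent were higher, against 31.9 percent without a filter on low counts. MAPK output genes rose in 4 of 9, with a score of 0.51 ± 0.04 (9 of 9 libraries, exact permutation p = 1.72e-05, adjusted p = 0.000147). In the 5 receptor lines FOSL1 (3.68 ± 0.38), ETV4 (3.66 ± 0.27), IVL (3.04 ± 0.16), DUSP6 (2.84 ± 0.18) and KRT18 (1.31 ± 0.07) rose. KRT4 (−2.47 ± 0.25), ESR1 (−1.29 ± 0.08), PGR (−1.10 ± 0.09) and GREB1 (−0.89 ± 0.07) fell. MAPK output genes rose in 14 of 16 (1 fell), luminal identity genes in 9 of 14 (1 fell) and stress genes in 7 of 13 (1 fell), and cholesterol synthesis genes fell in 8 of 14 (1 rose). Of 11770 genes tested 22.1 percent were higher and 24.7 percent lower (n = 28 and 30). FIIN-3 on top of palbociclib and FGF2 lowered SPRY4 (−4.67 ± 0.28), DUSP6 (−4.15 ± 0.20), IVL (−3.92 ± 0.14), IFIT3 (−3.76 ± 0.46) and CCND1 (−1.67 ± 0.08). Raised were KRT4 (3.02 ± 0.22), OLR1 (2.90 ± 0.18), HMGB2 (2.54 ± 0.13), ESR1 (1.32 ± 0.09) and PGR (1.41 ± 0.08). MAPK output genes fell in 14 of 16 (1 rose) and interferon genes in 11 of 17 (score −0.80 ± 0.17, 22 of 29 libraries, permutation p = 5e-05, adjusted p = 0.000328). In FGFR1 the score was at 0.36 ± 0.16. Of 11780 genes tested 29.4 percent were higher and 27.3 percent lower (n = 29 and 28).

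FIIN-3 alone was measured in both sets in the FGF3 and N550K lines, which shows how far the sets differ for the same labels. The nucleotide carrier SLC25A6 (13.84 ± 0.22), the adhesion protein CD99 (10.99 ± 0.24), DHRSX (9.63 ± 0.37) and ZBED1 (7.86 ± 0.30), which lie in the pseudoautosomal region shared by the X and Y chromosomes, were higher in set 2, as was PRODH (8.74 ± 0.38), which lies outside it. ISG15 was lower (−2.71 ± 0.67). Cholesterol synthesis genes split into 8 higher and 3 lower of 14 (score 0.32 ± 0.06, 11 of 11 libraries, permutation p = 3e-05, adjusted p = 0.000202), and luminal identity genes into 2 higher and 8 lower of 14. For ribosome biogenesis the score (−0.17 ± 0.05, adjusted p = 0.00355) and the median gene (0.01) differed in sign. Of 11171 genes tested 26.6 percent were higher and 24.4 percent lower (n = 11 and 12), so no treatment effect is read across the sets.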

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

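Tests chosen only after the result was seen were the position test for the libraries with a low MT-RNR2 share, both tests for the pseudoautosomal genes and the 4 interaction tests of the interferon score under trametinib and FIIN-3; the others were written down before.

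In 16 libraries MT-RNR2 took 1.09 to 4.43 percent of counts (median 1.43), against 5.49 percent or more (median 18.5) in all others. Of these, 14 were in set 1 and all 14 lay in the third range of 96 title numbers, with 93 libraries (Fisher's exact test, p = 1.46e-09). A step shared by neighbouring samples fits, although the labels name no batch. Against the rest of their groups, gene length (median Spearman rho −0.265), GC content (−0.161) and total count (median ratio 0.779) left each of the 3 open as a part of the cause. Of the 16, 8 were DMSO libraries, among 45 at DMSO in set 1. All 8 lay in the third range, and no DMSO library of set 1 outside it stood apart, which argues against DMSO by itself as the cause. A change in the cells of that range cannot be told apart from handling. No biological explanation was tested.

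Pseudoautosomal genes were almost without counts in set 1: of 18 protein-coding genes, 11 had at least 1 CPM in set 2, and of these 6 had 0 reads and all 11 had under 100 reads in set 1 (0.0316 percent of the reads in set 2). Of X-linked genes outside these regions 0 percent were as low, which fits reads with an identical copy on the Y chromosome being left uncounted in set 1. The tables argue against depth, since the median total of set 1 was 2.62 times that of set 2. The processing notes name STAR and hg19 but not the counting program, its annotation or the versions, so a difference in reference files stays open. No biological explanation was tested.

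Interferon response genes rose with trametinib in the FGFR2 lines and not in the control lines (difference of the effect on the score 1.73, permutation p = 1e-05, adjusted p = 1.33e-05), which was marked as a difference between groups. The tables argue against depth, since thinning 46 libraries to 4469662 counts, with 2 low-depth libraries left out, kept 100 percent of the change (1.22 before and after). They also argue against position, as the change was 1.01 and 1.35 within the ranges that held both arms, against 1.23 pooled. They argue against 1 receptor line carrying the rise, as 3 of the 4 FGFR2 lines passed after adjustment by line, but K660N did not (0.56, exact permutation p = 0.0368, adjusted p = 0.0909). Signaling of overexpressed FGFR2 in the presence of a MEK block stays open as a biological explanation and was not tested.

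Other differences in the interferon score between the FGFR2 and the control lines were marked for FIIN-3 in set 1 (−0.85) and for trametinib against FIIN-3 under fulvestrant, palbociclib and FGF2 in set 2 (2.31; both permutation p = 1e-05 and adjusted p = 1.33e-05). The trametinib effect in the FGFR1 line differed from the control lines by −0.23 (permutation p = 0.929). Within the difference of 2.31, in groups that no comparison of the report used, the score of the FGFR2 lines was higher by 1.94 with trametinib than with FIIN-3. This does not show a rise with trametinib by itself, since FIIN-3 lowered the score in set 1.

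For the response to fulvestrant, differences from the control lines were marked in the estrogen receptor target score of the FGFR2 lines (0.28) and of the FGF3 line (0.68), and in the G1/S (0.46) and ribosome biogenesis (0.34) scores of the FGF3 line. For FGF2 added to fulvestrant they were marked in the FGFR1 line for MAPK output (1.07), G2/M (0.49), luminal identity (0.23), basal or mesenchymal (0.34) and ribosome biogenesis (0.32). In the FGFR2 lines they were marked for MAPK output (0.49), G1/S (−0.46), G2/M (−0.39), luminal identity (0.42), basal or mesenchymal (0.24) and ribosome biogenesis (0.27).

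Single libraries lay far from their group in the estrogen receptor target score by Dixon's ratio: N550K with fulvestrant, replicate 3 (0.735, a library that stands apart), M538I with fulvestrant and FGF2, replicate 6 (0.649), and N550K with fulvestrant and FGF2, replicate 5 (0.806). Of 52 groups tested 3 were marked, and chance marks about 1 in 20 groups.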

How the results depend on the processing

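No analysis paired by replicate number was possible, because these numbers follow the order of deposition and the labels do not say that they link libraries across treatments. Title numbers of neighbouring libraries entered only as the block and range terms below. Fold changes of log2 size 1 in single lines were often missed at this depth and number of libraries: 26.8 percent were recovered in the simulation for K660N vs GFP. Every alternative fixed in advance was run, except limma where the second table's columns were not used, and removal of low-depth libraries where no library of a comparison was of low depth. Below, a pair of values gives the result as reported and under the alternative. Called genes are in percent of the genes tested in the reported comparison. The cause of each change was not tested unless stated.

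Without a filter on low counts, 17 of 41 counts of called genes left the range of 1.5 times the reported count. Parental vs GFP went from 0 to 2.15, FGFR1 vs GFP from 0.00787 to 0.0236 and wild type vs GFP from 0.00808 to 0.194. M538I vs GFP went from 0.0159 to 0.342, K660N vs GFP from 1.51 to 6.66 and FGF3 vs GFP from 7.18 to 12.7. M538I vs wild type went from 0 to 0.0160, N550K vs wild type from 0.460 to 0.871 and FGF2 vs DMSO in controls from 6.12 to 10.6. Fulv vs DMSO in controls went from 1.55 to 5.82, Fulv vs DMSO in FGFR1 from 0.0791 to 2.58 and Fulv vs DMSO in FGFR2 lines from 2.94 to 1.85. Fulv vs DMSO in FGF3 went from 0 to 0.510, the Fulv vs DMSO interaction in FGFR1 from 0 to 0.0288 and the Fulv vs DMSO interaction in FGFR2 lines from 0.00703 to 0.155. The Fulv vs DMSO interaction in FGF3 went from 0.00695 to 0.104 and Palbo+FGF2 vs Palbo in controls from 1.11 to 5.77. More genes are tested in that setting.

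With the DESeq2 Wald test 17 of 41 did. Parental vs GFP went from 0 to 1.32, FGFR1 vs GFP from 0.00787 to 0.0157 and wild type vs GFP from 0.00808 to 0.129. M538I vs GFP went from 0.0159 to 1.04, N550K vs GFP from 1.60 to 3.97 and K660N vs GFP from 1.51 to 3.15. FGF3 vs GFP went from 7.18 to 15, N550K vs wild type from 0.460 to 1.73 and K660N vs wild type from 16.2 to 25.1. FGF2 vs DMSO in controls went from 6.12 to 9.18, Fulv vs DMSO in controls from 1.55 to 2.82 and Fulv vs DMSO in FGFR1 from 0.0791 to 0.340. Fulv vs DMSO in FGFR2 lines went from 2.94 to 5.61, Fulv vs DMSO in FGF3 from 0 to 0.0289 and the Fulv vs DMSO interaction in FGF3 from 0.00695 to 0.0765. Palbo vs control in FGF3 went from 6.54 to 10.1 and Palbo+FGF2 vs Palbo in controls from 1.11 to 2.46.

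With the block term 14 of 41 did. Wild type vs GFP went from 0.00808 to 0.121, M538I vs GFP from 0.0159 to 1.06 and N550K vs GFP from 1.60 to 4.02. K660N vs GFP went from 1.51 to 2.32, M538I vs wild type from 0 to 0.0641 and N550K vs wild type from 0.460 to 4.18. K660N vs wild type went from 16.2 to 35.2, Fulv vs DMSO in FGFR1 from 0.0791 to 0.443 and Fulv vs DMSO in FGFR2 lines from 2.94 to 16.1. Fulv vs DMSO in FGF3 went from 0 to 0.0481, the Fulv vs DMSO interaction in FGF3 from 0.00695 to 0.0417 and the Fulv+FGF2 vs Fulv interaction in FGFR1 from 4.79 to 7.54. Fulv+FIIN-3 vs Fulv in FGF3 went from 13.1 to 20.1 and Fulv+Tram vs Fulv in FGF3 from 7.43 to 13.4.

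With limma on the deposited log2(TPM + 1) values 10 of 17 did. FGFR1 vs GFP went from 0.00787 to 0, wild type vs GFP from 0.00808 to 0, N550K vs GFP from 1.60 to 0.755 and FGF3 vs GFP from 7.18 to 3.51. N550K vs wild type went from 0.460 to 0.169, Fulv vs DMSO in controls from 1.55 to 0.572, Fulv vs DMSO in FGFR1 from 0.0791 to 0.0475 and Fulv vs DMSO in FGFR2 lines from 2.94 to 1.81. The Fulv vs DMSO interaction in FGFR2 lines went from 0.00703 to 0 and the Fulv vs DMSO interaction in FGF3 from 0.00695 to 0.132.

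Without the libraries that stand apart, chosen after seeing the data, 18 of 27 did. Parental vs GFP went from 0 to 0.0886, FGFR1 vs GFP from 0.00787 to 0.0315 and wild type vs GFP from 0.00808 to 0.0242. M538I vs GFP went from 0.0159 to 1.76, N550K vs GFP from 1.60 to 8.16 and K660N vs GFP from 1.51 to 3.30. FGF3 vs GFP went from 7.18 to 19, N550K vs wild type from 0.460 to 2.91 and K660N vs wild type from 16.2 to 4.39. FGF2 vs DMSO in controls went from 6.12 to 9.70, FGF2 vs DMSO in FGFR2 lines from 47.6 to 30.2 and Fulv vs DMSO in controls from 1.55 to 2.79. Fulv vs DMSO in FGFR1 went from 0.0791 to 0.206, the Fulv vs DMSO interaction in FGFR2 lines from 0.00703 to 0.0141 and the Fulv vs DMSO interaction in FGF3 from 0.00695 to 0.0278. The Fulv+FGF2 vs Fulv interaction in FGFR2 lines went from 3.23 to 5.24, Palbo vs control in FGF3 from 6.54 to 14.8 and Palbo+FGF2 vs Palbo in controls from 1.11 to 3.72.

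With the range term, also chosen after seeing the data, 10 of 26 did. FGF2 vs DMSO in FGFR2 lines went from 47.6 to 24.5, Fulv vs DMSO in FGFR1 from 0.0791 to 0.443, Fulv vs DMSO in FGFR2 lines from 2.94 to 16.1 and Fulv vs DMSO in FGF3 from 0 to 0.0481. The Fulv vs DMSO interaction in FGF3 went from 0.00695 to 0.0417, the Fulv+FGF2 vs Fulv interaction in FGFR1 from 4.79 to 9.57, the Fulv+FGF2 vs Fulv interaction in FGFR2 lines from 3.23 to 5.65 and Fulv+FGF2+Tram vs Fulv+FGF2 in FGFR1 from 11.3 to 6.56. Fulv+FIIN-3 vs Fulv in FGF3 went from 13.1 to 20.1 and Fulv+Tram vs Fulv in FGF3 from 7.43 to 13.4.

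Without libraries of low depth 3 of 14 did. FGF3 vs GFP went from 7.18 to 0.124, FIIN-3 vs DMSO in FGF3 from 10.4 to 1.49 and Palbo vs control in FGF3 from 6.54 to 14.8. That leaves 1 DMSO library of the FGF3 line, assumed to vary like the other group, and no exact test of a list score against it can then pass.

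With DESeq2 size factors 1 of 41 did. M538I vs GFP went from 0.0159 to 0.0795.

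With the median over the list in place of the mean, 63.2 percent of list scores kept their direction and side of the threshold. Of the others 52 no longer passed, 16 newly passed, 99 moved and 14 changed sign. The estrogen receptor target score no longer passed for N550K vs GFP (from −0.63 to −0.40), K660N vs GFP (from −0.35 to −0.24), Fulv vs DMSO in FGFR1 (from −0.75 to −0.72) and the Fulv vs DMSO interaction in FGFR2 lines (from 0.28 to 0.19). A pass was lost in the estrogen receptor target score for the Fulv vs DMSO interaction in FGF3 (from 0.68 to 0.51), Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in FGFR2 lines (from −0.24 to −0.12) and Palbo+FGF2 vs Palbo in the receptor lines (from −0.18 to −0.17). A pass was gained in MAPK output for FGF3 vs GFP (from 0.64 to 1.51) and M538I vs wild type (from 0.39 to 0.65). Newly past the threshold was estrogen receptor target for Palbo+FGF2 vs Palbo in controls (from −0.17 to −0.36). Without passing, MAPK output moved for wild type vs GFP (from −0.0012 to 0.078), Fulv vs DMSO in controls (from 0.012 to −0.068) and Fulv vs DMSO in FGF3 (from 0.36 to −0.0021). Short of the threshold throughout, MAPK output moved for the Fulv vs DMSO interaction in FGFR1 (from −0.072 to 0.0038) and Fulv+FGF2+Tram vs Fulv+FGF2+FIIN-3 in the receptor lines (from −0.13 to 0.0043). With no pass in either, estrogen receptor target moved for FGF2 vs DMSO in controls (from 0.022 to −0.077), Fulv+FGF2 vs Fulv in controls (from 0.057 to −0.10) and Fulv+FGF2 vs Fulv in FGFR1 (from 0.17 to −0.11). The estrogen receptor target score moved without passing for the Fulv+FGF2 vs Fulv interaction in FGFR1 (from 0.10 to −0.017), Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in controls (from −0.12 to 0.065) and Fulv+FIIN-3 vs Fulv in FGF3 (from −0.085 to 0.26). Without passing, estrogen receptor target moved for Fulv+Tram vs Fulv in FGF3 (from −0.024 to 0.19), Palbo vs control in FGF3 (from 0.061 to −0.23) and set 2 vs set 1 (from 0.024 to −0.042). The sign of basal or mesenchymal changed for FGF2 vs DMSO in FGFR2 lines (from 0.19 to −0.086), Fulv+FGF2 vs Fulv in FGFR1 (from 0.35 to −0.065), Fulv+FGF2 vs Fulv in FGFR2 lines (from 0.23 to −0.0091) and Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in FGFR1 (from −0.29 to 0.42). A change of sign in estrogen receptor target was found for Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in FGFR1 (from −0.21 to 0.037), Fulv+FGF2+Tram vs Fulv+FGF2 in controls (from −0.19 to 0.052), Fulv+FGF2+Tram vs Fulv+FGF2 in FGFR2 lines (from −0.22 to 0.045) and Fulv+Palbo+FGF2 vs Fulv+FGF2 in 7 lines (from −0.14 to 0.026). Opposite in sign was luminal identity for Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in FGFR2 lines (from 0.12 to −0.052), Fulv+FGF2+Tram vs Fulv+FGF2 in FGFR2 lines (from 0.033 to −0.34), Palbo+FGF2 vs Palbo in controls (from −0.11 to 0.28) and set 2 vs set 1 (from −0.25 to 0.014). With the other sign was other cell types for Fulv+FGF2+Tram vs Fulv+FGF2+FIIN-3 in the receptor lines (from 0.16 to −0.060). The sign of ribosome biogenesis changed for Palbo+FGF2 vs Palbo in the receptor lines (from 0.18 to −0.061).

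With scores from the second table, 71.1 percent of list scores kept their direction and side of the threshold. Of the others 22 no longer passed, 2 newly passed, 35 moved and 0 changed sign. Past the threshold before but not here was MAPK output for N550K vs GFP (from 1.00 to 0.57) and N550K vs wild type (from 1.00 to 0.62). Lost passes of estrogen receptor target were in N550K vs GFP (from −0.63 to −0.38), K660N vs GFP (from −0.35 to −0.017), FGF3 vs GFP (from −0.89 to −0.24) and Fulv vs DMSO in FGFR1 (from −0.75 to −0.46). The estrogen receptor target score no longer passed for Fulv vs DMSO in FGFR2 lines (from −0.42 to −0.23), the Fulv vs DMSO interaction in FGFR2 lines (from 0.28 to 0.27) and the Fulv vs DMSO interaction in FGF3 (from 0.68 to 0.49). Gained passes of MAPK output were in FGF3 vs GFP (from 0.64 to 0.73). Short of the threshold throughout, estrogen receptor target moved for K660N vs wild type (from −0.14 to 0.13) and the Fulv vs DMSO interaction in FGFR1 (from −0.057 to 0.043). With no pass in either, MAPK output moved for Fulv vs DMSO in FGFR1 (from −0.063 to 0.056) and the Fulv vs DMSO interaction in FGFR1 (from −0.072 to 0.019).

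Without the libraries that stand apart, 75 percent of list scores kept their direction and side of the threshold. Of the others 11 no longer passed, 20 newly passed, 49 moved and 1 changed sign. A pass was lost in the MAPK output score for N550K vs wild type (from 1.00 to 1.06). Short of the threshold before but not here was estrogen receptor target for parental vs GFP (from −0.13 to −0.24), FGF2 vs DMSO in FGFR1 (from −0.15 to −0.30), FGF2 vs DMSO in FGFR2 lines (from −0.028 to −0.15) and Palbo+FGF2 vs Palbo in controls (from −0.17 to −0.22). A pass was gained in MAPK output for FGF3 vs GFP (from 0.64 to 0.78). The MAPK output score moved without passing for FGFR1 vs GFP (from −0.19 to 0.021), wild type vs GFP (from −0.0012 to 0.28), Fulv vs DMSO in FGFR2 lines (from 0.089 to −0.015) and the Fulv vs DMSO interaction in FGFR2 lines (from 0.085 to −0.087). Without passing, estrogen receptor target moved for FGF2 vs DMSO in controls (from 0.022 to −0.034). A change of sign in other cell types was found for N550K vs GFP (from −0.011 to 0.22). With 4 libraries left on each side for N550K vs wild type, and 3 and 5 for M538I vs GFP, no list score could pass after adjustment.

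Without libraries of low depth, 80.4 percent of list scores kept their direction and side of the threshold. Of the others 15 no longer passed, 1 newly passed, 17 moved and 0 changed sign. Past the threshold before but not here was estrogen receptor target for FGF3 vs GFP (from −0.89 to −0.91) and the Fulv vs DMSO interaction in FGF3 (from 0.68 to 0.73). Lost passes of MAPK output were in FIIN-3 vs DMSO in FGF3 (from −0.58 to −0.86) and Fulv+FIIN-3 vs Fulv in FGF3 (from −1.10 to −1.20). Short of the threshold throughout, estrogen receptor target moved for Fulv vs DMSO in FGF3 (from −0.031 to 0.044). No list score could pass for FGF3 vs GFP and FIIN-3 vs DMSO in FGF3, with 1 DMSO library left, or for Fulv+FIIN-3 vs Fulv in FGF3, with 3 libraries left on each side.

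With DESeq2 size factors, 89.6 percent of list scores kept their direction and side of the threshold. Of the others 6 no longer passed, 19 newly passed, 26 moved and 0 changed sign. The estrogen receptor target score no longer passed for Fulv+FGF2+FIIN-3 vs Fulv+FGF2 in FGFR1 (from −0.21 to −0.18). Newly past the threshold was estrogen receptor target for M538I vs GFP (from −0.45 to −0.46), N550K vs wild type (from −0.43 to −0.46) and Palbo+FGF2 vs Palbo in controls (from −0.17 to −0.19). Gained passes of MAPK output were in Fulv+FGF2+Tram vs Fulv+FGF2+FIIN-3 in the receptor lines (from −0.13 to −0.15). With no pass in either, estrogen receptor target moved for FGF2 vs DMSO in controls (from 0.022 to −0.033) and Fulv+FGF2+Tram vs Fulv+FGF2+FIIN-3 in the receptor lines (from 0.025 to −0.0006). The MAPK output score moved without passing for Fulv vs DMSO in controls (from 0.012 to −0.028).

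Of 6781 values of named genes over these settings, 95.3 percent kept direction and side of the threshold, 1.83 percent no longer passed, 1.61 percent newly passed and 87 moved. The 1 value that changed sign was FGFR2 in FGF2 vs DMSO in FGFR2 lines, from 0.83 to −0.0079 with the range term. The log2 ratio of FGF3 between its line and GFP at DMSO went from 7.05 to 8.45 in the second table.

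Leaving out each library in turn where an arm had 5 or fewer gave ranges of called genes, in percent of the genes tested. The percent ran from 0.00787 to 0.0157 for FGFR1 vs GFP, 0.0159 to 0.405 for M538I vs GFP and 3.48 to 19 for FGF3 vs GFP. The percent ran from 0 to 0 for M538I vs wild type, 22.2 to 36.8 for FGF2 vs DMSO in FGFR1 and 0.0317 to 0.206 for Fulv vs DMSO in FGFR1. The percent ran from 0 to 0.00962 for Fulv vs DMSO in FGF3, 0 to 0 for the Fulv vs DMSO interaction in FGFR1 and 0.00695 to 0.0278 for the Fulv vs DMSO interaction in FGF3. The percent ran from 7.06 to 10.7 for FIIN-3 vs DMSO in FGF3, 9.27 to 13.3 for Fulv+FIIN-3 vs Fulv in FGF3 and 5.02 to 8 for Fulv+Tram vs Fulv in FGF3. Of 3468 values of named genes in these fits, 3283 kept direction and side of the threshold. Of the others 78 no longer passed, 14 newly passed, 92 moved and 1 changed sign. It was FGF3 in its own line for Fulv+FIIN-3 vs Fulv, from −0.10 to 0.45 without fulvestrant replicate 4 (lowest −0.28, without replicate 3).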

Other observations

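Tests chosen only after the result was seen were those of the first paragraphs here, on groups outside the comparisons of the report, and the splits of the libraries for 14 of the 41 comparisons. These 14 were the DMSO comparisons of lines, FGF2 against DMSO, and fulvestrant against DMSO in the control lines. FIIN-3 added to FGF2 without fulvestrant lowered the MAPK output and cell cycle scores in the 5 receptor lines of set 1. The MAPK output score changed by −1.72 ± 0.07, G1/S by −1.03 ± 0.08 and G2/M by −1.48 ± 0.09. Ribosome biogenesis changed by −0.33 ± 0.02 and the interferon response by −0.72 ± 0.15 (lower in 4 of 5 lines). Estrogen receptor targets rose by 0.17 ± 0.05 (29 and 30 libraries; adjusted permutation p at most 0.00062). In the control lines MAPK output (−0.80 ± 0.05), G1/S (−1.02 ± 0.05) and G2/M (−1.66 ± 0.09) fell and luminal identity rose (0.42 ± 0.05). The interferon score was at −0.10 ± 0.07 (permutation p = 0.154; 12 and 12 libraries).

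Under fulvestrant, palbociclib and FGF2 in set 2, trametinib left the FGFR2 lines with higher scores than FIIN-3 for the interferon response (1.94 ± 0.19), cholesterol synthesis (0.46 ± 0.03), G1/S (0.43 ± 0.05), ribosome biogenesis (0.32 ± 0.03) and stress (0.29 ± 0.04). It left lower scores for MAPK output (−0.33 ± 0.05) and for receptors and adaptors (−0.39 ± 0.05; 23 and 22 libraries; permutation p = 1e-05, adjusted p = 2.29e-05 each, the smallest possible). For MAPK output N550K had the largest difference, with means of 2.02 with FIIN-3 and 1.25 with trametinib, against 1.41 to 1.46 and 1.18 to 1.36 in the other 3 lines. In the control lines, scores also differed for MAPK output (−0.22 ± 0.06, adjusted permutation p = 0.00203), cholesterol synthesis (0.46 ± 0.04), G2/M (0.72 ± 0.09, against 0.34 ± 0.12 in the FGFR2 lines) and receptors and adaptors (−0.39 ± 0.06). Their interferon score was at −0.37 ± 0.19 (adjusted permutation p = 0.0645; 12 and 11 libraries).

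Each comparison was repeated on 20 random splits of its own libraries (21 with the real one), not on all, for time. In 34 of 41 comparisons the real split alone (1 of 21) reached its count. As the smallest share possible, this does not exclude chance over 41 comparisons. For parental against GFP (0 calls, highest other split 0), M538I against wild type (0 and 0), the interaction of fulvestrant with FGFR1 (0 and 0) and fulvestrant in the FGF3 line (0 and 21) the splits tell nothing, as no split can have fewer than 0 calls. Against GFP, 2 of 21 splits were as large for wild type (1 call, highest other split 1387) and 4 for M538I (2 and 2629). For N550K 2 were (1.60 percent of genes tested and 937 calls). In each of these, the split with the most calls put all 3 libraries that stand apart on 1 side. FGFR2, called in all 3, was at 43.5 CPM or more there and at most 21.5 in GFP, which argues against chance for FGFR2. Among the 34, the highest other splits were 1564 for FIIN-3 on fulvestrant and FGF2 in the FGFR1 line (real 3639) and 1117 for FGF2 under palbociclib in the receptor lines (5516). They were 491 and 461 for FGF2 under fulvestrant in the control lines (1567) and the FGFR1 line (3330).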
